A study of Mus musculus with 44 samples.

How the data were processed

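Gene expression was measured on 44 Affymetrix arrays of liver, spleen and bone marrow of B6C3F1 mice, a hybrid laboratory mouse strain, given 2-butoxyethanol (2BE), a glycol ether solvent, or vehicle. Per the labels, tissue was taken at 4 h (liver and spleen) or at 7 d (liver, spleen and bone marrow). The titles name the arms 2BE and vehicle, while the treatment field calls the 2BE samples reduced oxygen and the vehicle samples control. The groups follow the titles, and the sources used here give no dose or route. Per the labels, RNA of liver and spleen was purified on mini columns and RNA of marrow with a marrow RNA kit, and it was labelled with biotin by a one-cycle protocol.

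The values are intensity per probe set, as the authors deposited them in 1 table. Per the submitters' processing notes they were made with RMA, which corrects the background, normalizes the arrays by quantiles and summarises the probes of a probe set; its version is not given in the sources used here. The table was on a linear scale, from 6.16 to 47797.8 with 0 missing values, and values were analysed as log2(intensity + 1), so that fold changes are on the log2(value + 1) scale, which understates the change of low genes. Medians over all probe sets lay at 41.2 to 42.4 in the liver at 4 h, 86.9 to 89.1 in the spleen at 4 h, 50.0 to 52.2 in the liver at 7 d, 86.1 to 89.4 in the marrow and 109 to 112 in the spleen at 7 d. They formed 5 sets, so the sets of a tissue and time may have been normalized separately. Levels were therefore compared only within a set, and times and tissues by differences of the 2BE-minus-vehicle differences. The number of arrays limits the precision.

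Of 45101 probe sets, 64 controls were left out. Of the other 45037, the platform annotation gave 1 gene symbol for 34945, several for 932 and none for 9160. Gene IDs of 34754 probe sets were looked up in a current gene table, and 0 symbols changed. Each of the 18193 genes was represented by the probe set with the highest mean over all arrays. Probe sets with several symbols or with none entered no gene test, and the latter were counted on their own.

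Models were fitted with limma 3.58.1 in R 4.3.3: lmFit on group means for each tissue, over 4 groups of liver, 4 of spleen and 2 of marrow, and eBayes with no trend and no robust option. Tests were two-sided, with Benjamini-Hochberg (BH) adjustment over the 18193 genes, and a gene was called changed at an adjusted p under 0.05. Time differences were contrasts within a tissue fit, and tissue differences were contrasts in a fit over the arrays of 1 time point. SE is limma's moderated standard error. For each comparison, 24 gene lists and 18 cell-type marker lists were tested with camera at a preset correlation of 0.01, with BH adjustment over the 42 lists of a comparison. Camera with an estimated correlation served as a check. So did fry, which asks whether a list's genes move on balance in one direction and compares them with no other genes. Some lists share members: Cdkn1a, Dusp1 and Per1 of the glucocorticoid response list also belong to the p53, immediate early and clock lists.

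The 42 lists were hypoxia-induced glycolysis, other hypoxia-inducible genes, haem synthesis, erythroid cells, iron and haem handling, cell cycle, angiogenic signalling, endothelial cells, coagulation and fibrinolysis, acute phase response, Nrf2 antioxidant response, p53 targets, fatty acid oxidation and PPARa targets, hepatic cytochromes P450 and conjugation, cholesterol synthesis, lipogenesis, ER stress and integrated stress response, heat shock proteins, interferon response, inflammatory cytokines and NF-kB targets, immediate early genes, circadian clock, glucocorticoid response, extracellular matrix, B cells, B cell precursors, plasma cells, T cells, NK cells, neutrophils, granulocyte progenitors, macrophages, megakaryocytes and platelets, eosinophils, basophils and mast cells, haematopoietic stem and progenitor cells, hepatocytes, cholangiocytes, stellate cells and fibroblasts, adipocytes, bone cells, pancreatic acinar cells and skeletal muscle. The groups, tests, lists, alternatives and the rule for the genes named were fixed before the data were examined. The rule took up to 8 genes with the largest rise and 8 with the largest fall whose 2BE arrays all lay on one side of all vehicle arrays. They also had to exceed the median of all probe sets of the tissue in the higher group, and clone-like symbols were left out. It added up to 4 members of each list with the largest change among those passing, and always Hmox1, Hamp, Vegfa, Alas2, Tfrc, Cdkn1a and Mki67. For each difference it took up to 5 genes per direction. Fewer could be named, in order of size.

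Replicate numbers recur in both arms. Their deviations from the group means correlated at 0.132 to 0.282 in the 3 same-numbered pairs of the liver at 4 h, so the numbers were taken to pair these arrays; elsewhere the numbers were not taken to pair them. Whether tissues with 1 number came from 1 mouse was not stated. Nothing in the labels says how replicates were obtained beyond their numbers, so p-values measure only the spread between these samples, which may be technical. Within groups, arrays had r of 0.983 to 0.998. Between arms, 3' to 5' ratios of Gapdh and actin controls did not pass (lowest adjusted p = 0.847, exact two-sided permutation tests). With so few arrays none could pass alone.

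The fits were tested on simulated data with 200 changed genes among 18193. At a log2 change of 1, 97.0% (spleen at 4 h) to 100% (marrow) of them were called. At 0.5 the shares were 70.1% (both tissues at 4 h) to 91.0% (marrow). For differences they were 26.9% (spleen times) to 74.6% (marrow and liver). Recovery in the real data, where genes of 1 cell type vary together, was not tested. Alternatives were a further quantile normalization within the tissue, subtraction of array medians, a filter on low values, all probe sets, the probe set highest within the tissue, eBayes with trend and robust, only the arrays of the 2 groups compared, array weights, the replicate number as a block, all 44 arrays in 1 fit, treatment and number as 1 mouse (random block, statmod 1.5.0), a size limit of 2-fold in both comparisons of an overlap, and leaving out each array in turn. Logs with no pseudocount were added after the data were seen. Splits of the arrays into other groups were drawn with a fixed seed, at most 100 per comparison.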

Results

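The data comprised 44 arrays in 10 groups. In the liver at 4 h there were 3 vehicle and 4 2BE arrays, and in the spleen at 4 h 4 and 4. At 7 d there were 4 vehicle and 5 2BE arrays of liver, 5 and 5 of bone marrow and 5 and 5 of spleen. The 5 comparisons set 2BE against vehicle in each tissue at each time. 2BE is known as a solvent whose metabolite butoxyacetic acid lyses red blood cells in rodents. Values in brackets after a fold are log2 fold changes of 2BE over vehicle with their standard errors (SE). For each gene said to have risen or fallen, all 2BE arrays lay beyond all vehicle arrays in that direction unless stated otherwise. Rankings by size are among genes that the rule for naming took by size, whose arms did not overlap. Arrays named as left out were each left out alone. Adjusted p-values of genes came from limma with BH adjustment over 18193 genes, and those of lists from camera with BH adjustment over 42 lists.

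In the liver at 4 h, Hmox1, Igfbp1 and Cdkn1a rose most with 2BE (4 2BE and 3 vehicle arrays). Hmox1, which encodes the haem-degrading enzyme haem oxygenase 1, rose 9.45-fold (log2 fold change 3.24 ± 0.21 SE, adjusted p = 9.1e-07). Igfbp1, a secreted binding protein of insulin-like growth factors, rose 8.28-fold (3.05 ± 0.39, adjusted p = 0.000560), and Cdkn1a, a cyclin-dependent kinase inhibitor, rose 7.63-fold (2.93 ± 0.45, adjusted p = 0.00158). Cyp2b10, a drug-inducible cytochrome P450, rose 7.07-fold (2.82 ± 0.44), and the growth arrest gene Gadd45g rose 7.05-fold (2.82 ± 0.49). Ddit4, an inhibitor of mTOR signalling, rose 6.50-fold (2.70 ± 0.60, adjusted p = 0.0161), and thrombomodulin (Thbd) rose 6.26-fold (2.65 ± 0.34). The largest falls were those of Arrdc3, an arrestin-domain protein, by 11.8-fold (-3.56 ± 0.70, adjusted p = 0.00815), and of Socs2, a growth-hormone-inducible suppressor of cytokine signalling, by 8.73-fold (-3.13 ± 0.48, adjusted p = 0.00163), whose other probe sets were at -3.10 to -0.010.

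Stress-response lists rose in the liver at 4 h. Of 12 measured genes of the glucocorticoid response list, 10 rose over all genes and 11 when adjusted over the list alone (median log2 fold change 1.13, camera adjusted p = 6.0e-15; adjusted p = 0.00574 with an estimated correlation). Its members included Sgk1, a kinase induced by steroids (2.12 ± 0.41), and Dusp1, a phosphatase that restrains stress kinases (1.85 ± 0.27). Of 14 immediate early genes, 6 rose and 8 did so adjusted over the list alone (median log2 fold change 0.66, camera adjusted p = 5.1e-07; adjusted p = 0.0146 with an estimated correlation). Among them were the transcription factor genes Jun (2.13 ± 0.31, other probe set 1.43) and Fos (1.96 ± 0.37). Of 23 inflammatory cytokines and NF-kB targets, 7 rose, and adjusted over the list alone 9 rose and 1 fell (median log2 fold change 0.17, camera adjusted p = 4.2e-06; adjusted p = 0.0170 with an estimated correlation). The neutrophil chemokine Cxcl2 rose (1.89 ± 0.21), by a size that is uncertain since its vehicle mean of 4.21 lay near the lower quartile of all probe sets, and the NF-kB inhibitor gene Tnfaip3 rose 3.32-fold (1.73 ± 0.22), although its other probe set, at 0.49, did not pass. Among 24 other hypoxia-inducible genes 5 rose, also when adjusted over the list alone (median log2 fold change 0.16, camera adjusted p = 5.8e-05; adjusted p = 0.0146 with an estimated correlation). Igfbp1 and Ddit4 belong to it, and other stresses than hypoxia are known to induce both.

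Of 21 p53 targets 4 rose, and 6 adjusted over the list alone (median log2 fold change 0.11, camera adjusted p = 0.00367; adjusted p = 0.296 with an estimated correlation). It was led by Cdkn1a and the antiproliferative genes Btg2 (2.33 ± 0.31) and Trp53inp1 (2.26 ± 0.32). Cholesterol synthesis had 2 of 20 genes higher, and 2 adjusted over the list alone (median log2 fold change 0.25, camera adjusted p = 0.00367; adjusted p = 0.699 with an estimated correlation). Sqle, which encodes squalene epoxidase, stood at 1.06 ± 0.25 (adjusted p = 0.0211). In the Nrf2 antioxidant response list 3 of 23 rose and 1 fell, as they did adjusted over the list alone (median log2 fold change 0.13, camera adjusted p = 0.00872; adjusted p = 0.623 with an estimated correlation). Srxn1, encoding sulfiredoxin, rose 1.86-fold (0.90 ± 0.15), with other probe sets at 0.11 to 0.76, while Osgin1 fell 3.24-fold (-1.70 ± 0.32). Of 12 heat shock proteins 1 rose, and 2 adjusted over the list alone (median log2 fold change 0.12, camera adjusted p = 0.0213; adjusted p = 0.515 with an estimated correlation). The chaperone gene Hspa1a rose 5.38-fold (2.43 ± 0.17). The probe set of its near-identical neighbour Hspa1b was at 0.45, so these gave different values; cross-hybridization was not tested. The erythroid list had 0 of 29 genes changed (median log2 fold change -0.032, camera adjusted p = 0.445). Among genes fixed in advance, the iron-regulating hormone gene Hamp was at 0.31 ± 0.36 (adjusted p = 0.731) and Vegfa at -0.18 ± 0.091 (adjusted p = 0.330). Alas2 was at 0.14 ± 0.19 (adjusted p = 0.782), Tfrc at -0.073 ± 0.22 (adjusted p = 0.921) and Mki67 at -0.034 ± 0.16 (adjusted p = 0.952).

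In all, 821 genes changed in the liver at 4 h, 590 higher and 231 lower, of which 133 changed at least 2-fold (107 higher and 26 lower). Without vehicle replicate 1 or 2BE replicate 4 the count was 484 and 466, in this order. After a further quantile normalization the share of higher calls was 57.3%, against 71.9%. With the replicate number as a block, 471 genes and 13 lists passed, against 821 and 8. It lost 7 of 36 named gene calls, of the genes given above Ddit4 (adjusted p = 0.0643), Osgin1 (0.0512) and Sqle (0.0892). The lists gained with the block were macrophages and neutrophils, lower (adjusted p = 0.00155 and 0.0194), pancreatic acinar cells, lower (0.0253). Also gained were fatty acid oxidation and hepatic cytochromes P450, higher (0.0193 and 0.0194). Without 2BE replicate 2, 13 lists passed. With only the arrays of the 2 groups compared, 13 of the 36 gene calls were lost, of those given above Ddit4 (0.137), Sgk1 (0.122), Sqle (0.128), Srxn1 (0.0720) and Fos (0.0523) (adjusted p in brackets). Ddit4 was at 3.36 without 2BE replicate 1 and Sgk1 at 2.77 without vehicle replicate 3. Without 1 array 8 of the 36 were lost, of those given above Ddit4 without vehicle replicate 1 or 2BE replicate 4 (adjusted p = 0.0664 and 0.0525) and Sqle without vehicle replicate 1 or 2BE replicate 4 (adjusted p = 0.114 and 0.0703). List calls lost were those of cholesterol synthesis without vehicle replicate 1 (adjusted p = 0.304), Nrf2 antioxidant response without vehicle replicate 3 (adjusted p = 0.787) and heat shock proteins without vehicle replicate 1 or 2BE replicate 3 (adjusted p = 0.276 and 0.0902). The low-value filter ended those of heat shock proteins (0.437), Nrf2 antioxidant response (0.1004) and p53 targets (0.0558).

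In the spleen at 4 h, inflammatory, heat shock and immediate early genes rose (4 arrays per arm). Cxcl2, a chemokine that attracts neutrophils, rose 44.1-fold (log2 fold change 5.46 ± 0.21 SE, adjusted p = 1.6e-11). The vehicle values of Cxcl2 and Il6 (log2 means 4.58 and 3.97) lay under the lower quartile of all probe sets, with no detection values used here, so the size of these folds is uncertain. The chaperone genes Hspa1a and Hspa1b rose 28.0-fold (4.81 ± 0.21, adjusted p = 4.3e-11) and 26.8-fold (4.74 ± 0.37, adjusted p = 8.7e-08). Ccn1, a matricellular protein gene, rose 26.0-fold (4.70 ± 0.22, adjusted p = 7.1e-11), and the chemokine gene Cxcl1 rose 22.3-fold (4.48 ± 0.24), with other probe sets at 1.33 to 7.01. The cytokine gene Il6 rose 19.9-fold (4.31 ± 0.40) and the monocyte chemokine gene Ccl2 rose 13.3-fold (3.73 ± 0.28). Falls were led by Ncr1, which encodes an activating receptor of natural killer (NK) cells, at 2.71-fold (-1.44 ± 0.18, adjusted p = 4.4e-05).

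Of 14 immediate early genes in the spleen at 4 h, 12 rose, and 12 adjusted over the list alone (median log2 fold change 1.36, camera adjusted p = 5.6e-26; adjusted p = 0.00560 with an estimated correlation). Fos stood at 3.20 ± 0.21 and Egr1, another early transcription factor gene, at 2.82 ± 0.22. Among 23 inflammatory cytokines and NF-kB targets 15 rose, and adjusted over the list alone 15 rose and 1 fell (median log2 fold change 0.68, camera adjusted p = 1.1e-19; adjusted p = 0.0186 with an estimated correlation). The glucocorticoid response list had 6 of 12 genes higher, 9 adjusted over the list alone (median log2 fold change 1.19, camera adjusted p = 5.4e-13; adjusted p = 0.00560 with an estimated correlation). Heat shock proteins had 6 of 12 higher, 9 adjusted over the list alone (median log2 fold change 0.29, camera adjusted p = 3.1e-12; adjusted p = 0.0186 with an estimated correlation). Of 18 extracellular matrix genes 6 rose, 7 adjusted over the list alone (median log2 fold change 0.27, camera adjusted p = 2.4e-07; adjusted p = 0.0556 with an estimated correlation). Of 20 cholesterol synthesis genes 8 rose, 10 adjusted over the list alone (median log2 fold change 0.25, camera adjusted p = 1.5e-06; adjusted p = 0.0260 with an estimated correlation). Of 21 p53 targets 5 rose, also adjusted over the list alone (median log2 fold change 0.056, camera adjusted p = 1.8e-05; adjusted p = 0.00560 with an estimated correlation). The polo-like kinase gene Plk3 stood at 2.07 ± 0.10, Plk2 at 1.95 ± 0.17 and Cdkn1a at 1.80 ± 0.12; the other probe set of Plk2 was at -0.34 and did not pass, and that of Cdkn1a was at 1.05. Among 24 other hypoxia-inducible genes 4 rose, 8 adjusted over the list alone (median log2 fold change 0.16, camera adjusted p = 0.000197; adjusted p = 0.0116 with an estimated correlation).

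The Nrf2 antioxidant response list had 5 of 23 genes higher and 1 lower in the spleen at 4 h, and adjusted over the list alone 5 and 1 (median log2 fold change 0.079, camera adjusted p = 0.000214; adjusted p = 0.119 with an estimated correlation). Srxn1 rose 3.41-fold (1.77 ± 0.17), with other probe sets at -0.10 to 1.35, and Osgin1 rose 2.37-fold (1.24 ± 0.15). The acute phase response list had 4 of 26 genes higher, 5 adjusted over the list alone (median log2 fold change 0.075, camera adjusted p = 0.0108; adjusted p = 0.503 with an estimated correlation). For NK cells 2 of 7 fell, 6 adjusted over the list alone (median log2 fold change -0.44, camera adjusted p = 0.000114; adjusted p = 0.149 with an estimated correlation). The granzyme gene Gzma was among them (-0.97 ± 0.20). For T cells 1 of 10 fell, 7 adjusted over the list alone (median log2 fold change -0.56, camera adjusted p = 0.000214; adjusted p = 0.460 with an estimated correlation). For B cells 0 of 10 changed, and 0 adjusted over the list alone (median log2 fold change -0.33, camera adjusted p = 0.0385; adjusted p = 0.683 with an estimated correlation). Interferon response had 1 of 23 lower, 4 adjusted over the list alone (median log2 fold change -0.19, camera adjusted p = 0.0234; adjusted p = 0.646 with an estimated correlation). Endothelial cells had 6 of 22 higher and 1 lower, 7 and 3 adjusted over the list alone (median log2 fold change 0.064, camera adjusted p = 0.0109; adjusted p = 0.632 with an estimated correlation). Its member Fabp4, also abundant in adipocytes, was at 2.81 ± 0.73 (adjusted p = 0.0289) and the adipocyte gene Adipoq at 2.18 ± 1.44 (adjusted p = 0.454), and a difference in the share of fat was not tested. For cell cycle 0 of 35 changed, also adjusted over the list alone (median log2 fold change 0.17, camera adjusted p = 0.0241; adjusted p = 0.808 with an estimated correlation).

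In all, 938 genes changed in the spleen at 4 h, 602 higher and 336 lower, and 137 changed at least 2-fold (129 higher and 8 lower). After a further quantile normalization the share of higher calls was 53.6%, against 64.2%. Hmox1 was at 0.83 ± 0.38 (adjusted p = 0.252), Hamp at -0.10 ± 0.10 (adjusted p = 0.652), Vegfa at -0.36 ± 0.16 (adjusted p = 0.246), and Alas2 at -0.51 ± 0.18 (adjusted p = 0.112). Tfrc was at -0.25 ± 0.29 (adjusted p = 0.697) and Mki67 at 0.13 ± 0.28 (adjusted p = 0.852). The erythroid list was not called (1 of 29 lower, camera adjusted p = 0.679). Vehicle replicate 3 had the highest mean over this list in its group (11.2, against 10.2 in the lowest array), and without it 1027 genes changed. List calls lost were those of B cells without vehicle replicates 1, 2 and 4 or 2BE replicates 3 and 4 (adjusted p = 0.129, 0.288, 0.0776, 0.126 and 0.202). Also lost were those of cell cycle without vehicle replicates 2 and 4 or 2BE replicates 3 and 4 (adjusted p = 0.796, 0.455, 0.255 and 0.630). The next were acute phase response without vehicle replicate 2 or 2BE replicate 1 (adjusted p = 0.0837 and 0.0501) and endothelial cells without vehicle replicate 3 or 2BE replicate 1 (adjusted p = 0.181 and 0.113). The last was interferon response without vehicle replicate 1 or 2BE replicates 2 and 4 (adjusted p = 0.0510, 0.124 and 0.202), also lost with array weights (0.0660). The low-value filter ended the calls of cell cycle (0.186) and endothelial cells (0.241), and a further quantile normalization that of cell cycle (0.0504). The granulocyte progenitor list, not called with all arrays (median -0.20, camera adjusted p = 0.919), was higher without vehicle replicate 3 (median 0.64, adjusted p = 0.0403).

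In the liver at 7 d, Cyp4a14 and Ppp1r3g had the largest rises (5 2BE and 4 vehicle arrays). Cyp4a14, a fatty acid hydroxylase of the P450 family, rose 13.9-fold (log2 fold change 3.79 ± 0.72 SE, adjusted p = 0.0213). Without vehicle replicate 4 it was at 2.91, below Ppp1r3g. Ppp1r3g, a glycogen-targeting subunit of a phosphatase, rose 10.4-fold (3.38 ± 0.34, adjusted p = 0.000423). The macrophage scavenger receptor gene Marco rose 4.55-fold (2.19 ± 0.43, adjusted p = 0.0236), the adhesion molecule gene Vcam1 rose 3.96-fold (1.99 ± 0.28, adjusted p = 0.00500) and Coq10b, a coenzyme Q binding protein gene, rose 3.94-fold (1.98 ± 0.26, adjusted p = 0.00359). Arntl, a core transcription factor of the circadian clock, fell 3.02-fold (-1.59 ± 0.31, adjusted p = 0.0243), and Id1, a target of bone morphogenetic protein signalling, fell 2.58-fold (-1.37 ± 0.24, adjusted p = 0.0131). Hamp, which encodes the iron-regulating hormone hepcidin and is induced by the same signalling, was at -1.32 ± 0.31 (adjusted p = 0.0645), with all 5 2BE arrays below all vehicle arrays.

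Macrophage markers in the liver at 7 d had 2 of 14 genes higher, and 11 adjusted over the list alone (median log2 fold change 0.55, camera adjusted p = 1.5e-11; adjusted p = 0.530 with an estimated correlation), Marco among them. Lipogenesis had 3 of 18 higher, 9 adjusted over the list alone (median log2 fold change 0.45, camera adjusted p = 1.9e-07; adjusted p = 0.530 with an estimated correlation). The erythroid list had 4 of 29 higher, and adjusted over the list alone 6 higher and 1 lower (median log2 fold change 0.036, camera adjusted p = 0.0151; adjusted p = 0.530 with an estimated correlation). The beta-globin gene Hbb-b2 stood at 1.66 ± 0.34 (adjusted p = 0.0303), but its other probe set was at 0.19 and did not pass. Bpgm, whose product makes the ligand that lowers haemoglobin's oxygen affinity, rose 1.70-fold (0.76 ± 0.12, adjusted p = 0.00672). Inflammatory cytokines and NF-kB targets had 3 of 23 higher, 4 adjusted over the list alone (median log2 fold change 0.026, camera adjusted p = 0.0474; adjusted p = 0.530 with an estimated correlation). Vcam1 is among them, and the chemokine gene Cxcl1 stood at 3.17 ± 0.68 (adjusted p = 0.0397) with arms that overlapped (4.02 without vehicle replicate 4; other probe sets 1.31 to 3.69, not passing). Iron and haem handling had 3 of 28 lower, and adjusted over the list alone 3 higher and 5 lower, with no shift of the list (camera adjusted p = 0.467).

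Lists with few members called on their own also shifted upward in the liver at 7 d. Cholesterol synthesis had 0 of 20 genes called, and 0 adjusted over the list alone (median log2 fold change 0.32, camera adjusted p = 2.1e-05; adjusted p = 0.537 with an estimated correlation). The acute phase response had 0 of 26, and 4 adjusted over the list alone (median log2 fold change 0.39, camera adjusted p = 5.9e-05; adjusted p = 0.661 with an estimated correlation). Cell cycle had 1 of 35 higher, 3 adjusted over the list alone (median log2 fold change 0.074, camera adjusted p = 0.00327; adjusted p = 0.530 with an estimated correlation). Glucocorticoid response had 2 of 12 higher, and 3 higher and 1 lower adjusted over the list alone (median log2 fold change 0.23, camera adjusted p = 0.0183; adjusted p = 0.530 with an estimated correlation). Hypoxia-induced glycolysis had 1 of 17 higher, also adjusted over the list alone (median log2 fold change 0.089, camera adjusted p = 0.0413; adjusted p = 0.530 with an estimated correlation). Extracellular matrix had 0 of 18 called, and 0 higher and 0 lower adjusted over the list alone (median log2 fold change 0.062, camera adjusted p = 0.0413; adjusted p = 0.530 with an estimated correlation).

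In all, 136 genes changed in the liver at 7 d, 92 higher and 44 lower, and 35 changed at least 2-fold (25 higher and 10 lower). These counts depended on single arrays. Without vehicle replicates 2, 3 and 4 or 2BE replicates 1, 2, 4 and 5, in this order, 36, 46, 75, 250, 76, 58 and 81 genes changed, and 8, 12, 21, 63, 16, 15 and 15 at least 2-fold. The call of Cyp4a14 was lost without vehicle replicate 2 or 2BE replicates 4 and 5 (adjusted p = 0.0511, 0.0557 and 0.0558). That of Marco was lost without vehicle replicates 1, 2, 3 and 4 or 2BE replicate 4 (adjusted p = 0.0664, 0.0757, 0.0812, 0.0650 and 0.0624). Arntl was lost without vehicle replicates 2, 3 and 4 or 2BE replicates 2, 4 and 5 (adjusted p = 0.0850, 0.106, 0.0580, 0.0643, 0.0734 and 0.0641). For Id1 this held without vehicle replicate 2 (adjusted p = 0.0563). Hbb-b2 did not pass without vehicle replicates 1, 2, 3 and 4 or 2BE replicates 2, 3 and 4 (adjusted p = 0.1001, 0.0705, 0.0623, 0.0971, 0.0850, 0.0704 and 0.0830). Neither did Cxcl1 without vehicle replicates 1, 2 and 3 or 2BE replicates 2, 3, 4 and 5 (adjusted p = 0.0908, 0.149, 0.170, 0.0908, 0.0752, 0.0970 and 0.0934). Ppp1r3g, Coq10b and Bpgm passed without each of the 9 arrays in turn and under every other alternative. Vcam1 passed without each array, but not with the probe set highest within the tissue (adjusted p = 0.0668), and its other probe sets were at 0.088 to 0.88. With that choice Hbb-b2 did not pass either (0.381). The other probe sets of Marco and Arntl, at 0.93 and 0.023, did not pass. Of the genes given here, trend and robust ended the calls of Cxcl1 (0.0952), Hbb-b2 (0.0787), Cyp4a14 (0.0693), Marco (0.0673) and Arntl (0.0591). The replicate block ended those of Cxcl1 (0.0768) and Arntl (0.0524), and the fit to only the 2 groups that of Cxcl1 (0.0506). Hamp passed without 2BE replicate 2 (adjusted p = 0.0341) or 4 (0.0420) and with array weights (0.0239).

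List calls lost in the liver at 7 d were those of erythroid cells without 2BE replicate 1 (adjusted p = 0.0533) and glucocorticoid response without vehicle replicate 2 or 2BE replicate 2 (adjusted p = 0.123 and 0.0632). That of extracellular matrix was lost without vehicle replicates 2 and 4 or 2BE replicates 1, 3 and 4 (adjusted p = 0.240, 0.0773, 0.0743, 0.0731 and 0.0913). Hypoxia-induced glycolysis was lost without vehicle replicates 3 and 4 or 2BE replicates 1 and 4 (adjusted p = 0.0694, 0.0728, 0.0901 and 0.0645). Inflammatory cytokines and NF-kB targets did not pass without vehicle replicates 2 and 4 or 2BE replicates 1, 4 and 5 (adjusted p = 0.0653, 0.0644, 0.0772, 0.0645 and 0.0791). The NF-kB list was also lost with array medians subtracted (0.0512), the probe set highest within the tissue (0.0709), array weights (0.0751) and the replicate block (0.0610). The low-value filter ended the calls of erythroid cells (0.176), extracellular matrix (0.132), hypoxia-induced glycolysis (0.0579) and glucocorticoid response (0.0528). Without 2BE replicate 1, 6 lists passed, against 10. None passed camera with an estimated correlation (3 at an unadjusted p under 0.05) or fry (7 at an unadjusted p under 0.05). Hmox1 was at 0.64 ± 0.19 (adjusted p = 0.130), but passed with only the 2 groups (0.0333), array weights (0.0411) and the replicate block (0.00948). Vegfa was at 0.038 ± 0.080 (adjusted p = 0.928), and Alas2 at 0.27 ± 0.17 (adjusted p = 0.625). Tfrc was at 0.017 ± 0.20 (adjusted p = 0.988), Cdkn1a at -0.24 ± 0.40 (adjusted p = 0.898) and Mki67 at 0.34 ± 0.14 (adjusted p = 0.360).

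**Figure D1:**
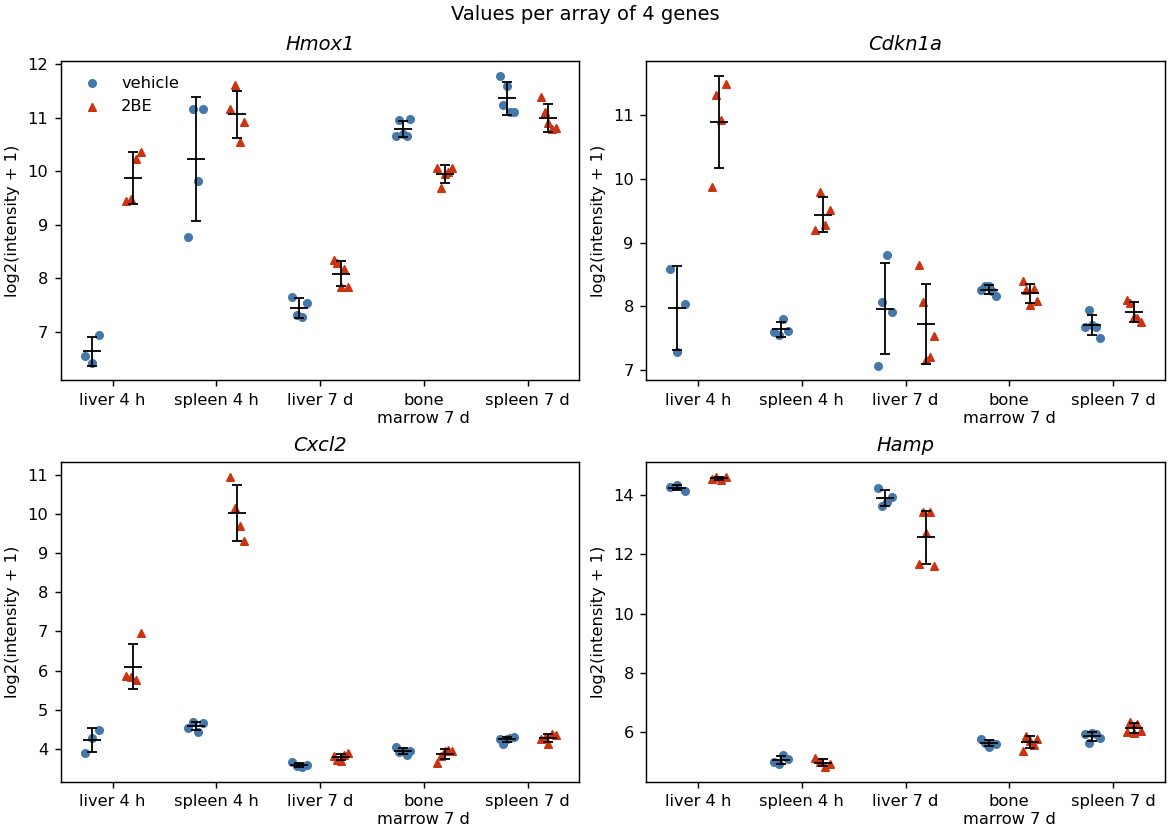
Values of Hmox1, Cdkn1a, Cxcl2 and Hamp per array, as log2(intensity + 1), by tissue and time (horizontal axis), with circles for vehicle, triangles for 2BE, and bars for mean and SD. Hmox1 lay at 9.44 to 10.4 in the liver at 4 h with 2BE against 6.42 to 6.94 with vehicle, Cxcl2 at 9.31 to 10.96 against 4.44 to 4.67 in the spleen at 4 h, and Hamp at 11.6 to 13.4 against 13.6 to 14.2 in the liver at 7 d.

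In the bone marrow at 7 d, B cell genes fell and erythroid genes rose (5 arrays per arm). Plek2, a pleckstrin-family gene active in late erythroid cells, rose 3.12-fold (log2 fold change 1.64 ± 0.10 SE, adjusted p = 2.1e-06), and Apol11b, of the apolipoprotein L family, rose 2.52-fold (1.33 ± 0.095). Cpm, a carboxypeptidase gene, fell 4.95-fold (-2.31 ± 0.28, adjusted p = 7.5e-05), and the fibrillar collagen gene Col11a1 fell 4.38-fold (-2.13 ± 0.33). Bach2, a transcription factor gene of B cells, fell 4.05-fold (-2.02 ± 0.22, adjusted p = 4.0e-05), with other probe sets at -1.96 to -0.36. Niban3, a gene of the niban family, fell 3.90-fold (-1.96 ± 0.21).

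All 10 measured B cell markers fell, also adjusted over the list alone (median log2 fold change -1.45, camera adjusted p = 5.8e-15; adjusted p = 0.323 with an estimated correlation). All 7 B cell precursor markers fell, and 7 adjusted over the list alone (median log2 fold change -1.20, camera adjusted p = 3.5e-09; adjusted p = 0.323 with an estimated correlation). Of 6 plasma cell markers 3 fell, 4 adjusted over the list alone (median log2 fold change -0.53, camera adjusted p = 0.00733; adjusted p = 0.323 with an estimated correlation). Of 29 erythroid genes 27 rose, 27 adjusted over the list alone (median log2 fold change 0.47, camera adjusted p = 3.4e-18; adjusted p = 0.323 with an estimated correlation). Of 11 haem synthesis genes 10 rose, 11 adjusted over the list alone (median log2 fold change 0.41, camera adjusted p = 1.1e-08; adjusted p = 0.323 with an estimated correlation). The transferrin receptor gene Tfrc rose 1.56-fold (0.64 ± 0.054). Of 35 cell cycle genes 28 rose, 29 adjusted over the list alone (median log2 fold change 0.23, camera adjusted p = 2.2e-15; adjusted p = 0.323 with an estimated correlation).

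Of 18 extracellular matrix genes in the marrow 10 fell, and adjusted over the list alone 1 rose and 11 fell (median log2 fold change -0.37, camera adjusted p = 0.000366; adjusted p = 0.629 with an estimated correlation). Stellate cells and fibroblasts had 5 of 10 lower, and 5 adjusted over the list alone (median log2 fold change -0.39, camera adjusted p = 0.00733; adjusted p = 0.323 with an estimated correlation). Macrophages had 3 of 14 lower, 6 adjusted over the list alone (median log2 fold change -0.20, camera adjusted p = 0.00733; adjusted p = 0.629 with an estimated correlation). T cells had 4 of 10 lower, 4 adjusted over the list alone (median log2 fold change -0.20, camera adjusted p = 0.00881; adjusted p = 0.519 with an estimated correlation). Eosinophils, basophils and mast cells had 3 of 5 lower, 3 adjusted over the list alone (median log2 fold change -0.31, camera adjusted p = 0.0104; adjusted p = 0.323 with an estimated correlation). Granulocyte progenitors had 1 of 5 lower, 5 adjusted over the list alone (median log2 fold change -0.25, camera adjusted p = 0.0347; adjusted p = 0.791 with an estimated correlation). The neutrophil list was not called (median -0.036, camera adjusted p = 0.713). Hmox1 fell 1.79-fold (-0.84 ± 0.087, adjusted p = 2.6e-05), and Mki67, a proliferation marker, rose 1.20-fold (0.27 ± 0.050). Hamp was at 0.015 ± 0.086 (adjusted p = 0.924), Vegfa at -0.086 ± 0.085 (adjusted p = 0.530), Alas2 at 0.16 ± 0.069 (adjusted p = 0.114) and Cdkn1a at -0.058 ± 0.071 (adjusted p = 0.623).

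In all, 3651 genes changed in the marrow, 1710 higher and 1941 lower, and 94 changed at least 2-fold (5 higher and 89 lower). The majority turned with array medians subtracted (2054 higher and 1577 lower) and after a further quantile normalization (2029 higher and 1928 lower). All 41 named calls passed without each array in turn. The list call lost was that of granulocyte progenitors without vehicle replicate 1 or 2BE replicates 2, 3 and 4 (adjusted p = 0.0556, 0.0917, 0.0546 and 0.0505). The low-value filter ended those of T cells (0.436), granulocyte progenitors (0.138) and eosinophils, basophils and mast cells (0.0582). No list passed camera with an estimated correlation (6 at an unadjusted p under 0.05), whereas fry called 10.

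The spleen at 7 d had the most changed genes, with erythroid and proliferation genes higher and lymphocyte genes lower (5 arrays per arm). Apol8, an apolipoprotein L family gene, rose 16.1-fold (log2 fold change 4.01 ± 0.42 SE, adjusted p = 2.5e-07). Sowaha, Mageb16 and Samd11 rose 15.4-fold (3.94 ± 0.33), 14.5-fold (3.85 ± 0.36) and 14.1-fold (3.81 ± 0.31), but the other probe set of Samd11 was at 0.99. Epb42, a red-cell membrane skeleton protein gene, rose 14.0-fold (3.81 ± 0.27, adjusted p = 2.5e-08). Clec2d, a lectin gene whose product is a ligand of an NK cell receptor, fell 5.81-fold (-2.54 ± 0.19, adjusted p = 2.8e-08). Klra8, an NK cell receptor gene, fell 4.76-fold (-2.25 ± 0.27), the immunoglobulin segment Igkv6-14 fell 4.36-fold (-2.13 ± 0.25) and Gzma fell 3.72-fold (-1.90 ± 0.18).

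All 29 measured erythroid genes rose in the spleen at 7 d, also adjusted over the list alone (median log2 fold change 2.98, camera adjusted p = 2.1e-14; adjusted p = 0.401 with an estimated correlation). The list's mean was at 11.9 to 12.3 in the 5 2BE arrays and at 8.40 to 9.87 in the vehicle arrays, of which replicate 1 was lowest. Without spleen 7 d vehicle replicate 1, changed genes spleen 7 d numbered 10873. All 11 haem synthesis genes rose, and 11 adjusted over the list alone (median log2 fold change 2.38, camera adjusted p = 2.9e-07; adjusted p = 0.401 with an estimated correlation). Urod, a haem pathway decarboxylase gene, rose 6.04-fold (2.59 ± 0.22), and Alas2, the erythroid first enzyme of the pathway, rose 2.18-fold (1.12 ± 0.16, adjusted p = 7.0e-06). Tfrc rose 6.01-fold (2.59 ± 0.26, adjusted p = 1.6e-07), with other probe sets at 3.85 to 3.91. All 35 cell cycle genes rose, again also adjusted over the list alone (median log2 fold change 2.30, camera adjusted p = 3.2e-15; adjusted p = 0.442 with an estimated correlation). The cyclin gene Ccne2 rose 9.50-fold (3.25 ± 0.32), the mitotic kinesin gene Kif11 rose 7.34-fold (2.88 ± 0.26) and Mki67 rose 5.19-fold (2.38 ± 0.25, adjusted p = 2.5e-07).

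All 10 B cell markers fell, also adjusted over the list alone (median log2 fold change -1.63, camera adjusted p = 9.0e-05; adjusted p = 0.502 with an estimated correlation). Of 10 T cell markers 9 fell and 1 rose, and 1 and 9 adjusted over the list alone (median log2 fold change -1.26, camera adjusted p = 0.00150; adjusted p = 0.502 with an estimated correlation). All 7 NK cell markers fell, 7 adjusted over the list alone (median log2 fold change -0.93, camera adjusted p = 0.00117; adjusted p = 0.401 with an estimated correlation). All 6 plasma cell markers fell, 6 adjusted over the list alone (median log2 fold change -1.21, camera adjusted p = 0.000422; adjusted p = 0.401 with an estimated correlation). Of 8 megakaryocyte and platelet markers 6 fell, 6 adjusted over the list alone (median log2 fold change -0.84, camera adjusted p = 0.0279; adjusted p = 0.682 with an estimated correlation). Macrophages were not called as a list (1 of 14 higher and 8 lower, camera adjusted p = 0.0569). Marco and Timd4, genes of resident macrophages, fell 2.53-fold (-1.34 ± 0.17) and 2.20-fold (-1.14 ± 0.15). The list was called lower without vehicle replicates 2 and 4 or 2BE replicates 3 and 5 (adjusted p = 0.0426, 0.0448, 0.0495 and 0.0412).

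Of 22 endothelial genes 18 fell, 19 adjusted over the list alone (median log2 fold change -0.79, camera adjusted p = 8.0e-06; adjusted p = 0.401 with an estimated correlation). Fabp4 stood at -2.32 ± 0.65 with arms that overlapped (-1.71 without vehicle replicate 2), and so did the adipocyte gene Adipoq, at -3.14 ± 1.29 (adjusted p = 0.0401). The adipocyte list was not called (median log2 fold change -0.55, camera adjusted p = 0.592; 0.00747 against lists matched on intensity). Pecam1, an endothelial junction gene, fell 2.27-fold (-1.18 ± 0.12). Angiogenic signalling had 4 of 28 higher and 19 lower, 5 and 19 adjusted over the list alone (median log2 fold change -0.85, camera adjusted p = 0.00117; adjusted p = 0.401 with an estimated correlation). Vegfa, the growth factor gene that hypoxia induces, fell 1.84-fold (-0.88 ± 0.14, adjusted p = 3.7e-05), but its other probe set, at -0.023, did not pass. Hypoxia-induced glycolysis had 1 of 17 higher and 12 lower, 1 and 12 adjusted over the list alone (median log2 fold change -0.63, camera adjusted p = 0.00387; adjusted p = 0.524 with an estimated correlation). The gene of pyruvate kinase (Pkm) fell 2.45-fold (-1.29 ± 0.14) and that of hexokinase 1 (Hk1) rose 2.44-fold (1.29 ± 0.14). Extracellular matrix had 1 of 18 higher and 13 lower, 1 and 13 adjusted over the list alone (median log2 fold change -0.54, camera adjusted p = 0.00260; adjusted p = 0.422 with an estimated correlation). Stellate cells and fibroblasts had 6 of 10 lower, 6 adjusted over the list alone (median log2 fold change -0.63, camera adjusted p = 0.0279; adjusted p = 0.401 with an estimated correlation). Of 9 pancreatic acinar markers 7 rose, 7 adjusted over the list alone (median log2 fold change 0.27, camera adjusted p = 0.0395; adjusted p = 0.502 with an estimated correlation and 0.272 against lists matched on intensity).

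In all, 11712 genes changed in the spleen at 7 d, 5896 higher and 5816 lower, and 1896 changed at least 2-fold (873 higher and 1023 lower). The balance depended on the processing. With the low-value filter 3054 higher and 5376 lower passed, and after a further quantile normalization 954 higher and 798 lower changed at least 2-fold. Hmox1 was at -0.37 ± 0.34 (adjusted p = 0.353) and passed with only the 2 groups (0.0468). Cdkn1a, at 0.21 ± 0.11 (adjusted p = 0.0908), passed after a further quantile normalization (0.0203) and without vehicle replicate 2 (0.0380). Hamp, at 0.27 ± 0.089 (adjusted p = 0.0121) and below array medians, did not pass after a further quantile normalization (0.0620). List calls lost were those of megakaryocytes and platelets without 2BE replicate 5 (adjusted p = 0.0516) and pancreatic acinar cells without 2BE replicate 2 (adjusted p = 0.0624). The low-value filter ended those of megakaryocytes and platelets (0.235), stellate cells and fibroblasts (0.223), extracellular matrix (0.0915), hypoxia-induced glycolysis (0.0915), pancreatic acinar cells (0.0915) and T cells (0.0568). A further quantile normalization ended that of pancreatic acinar cells (0.0795). No list passed camera with an estimated correlation (2 at an unadjusted p under 0.05), whereas fry called 29.

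**Figure D2:**
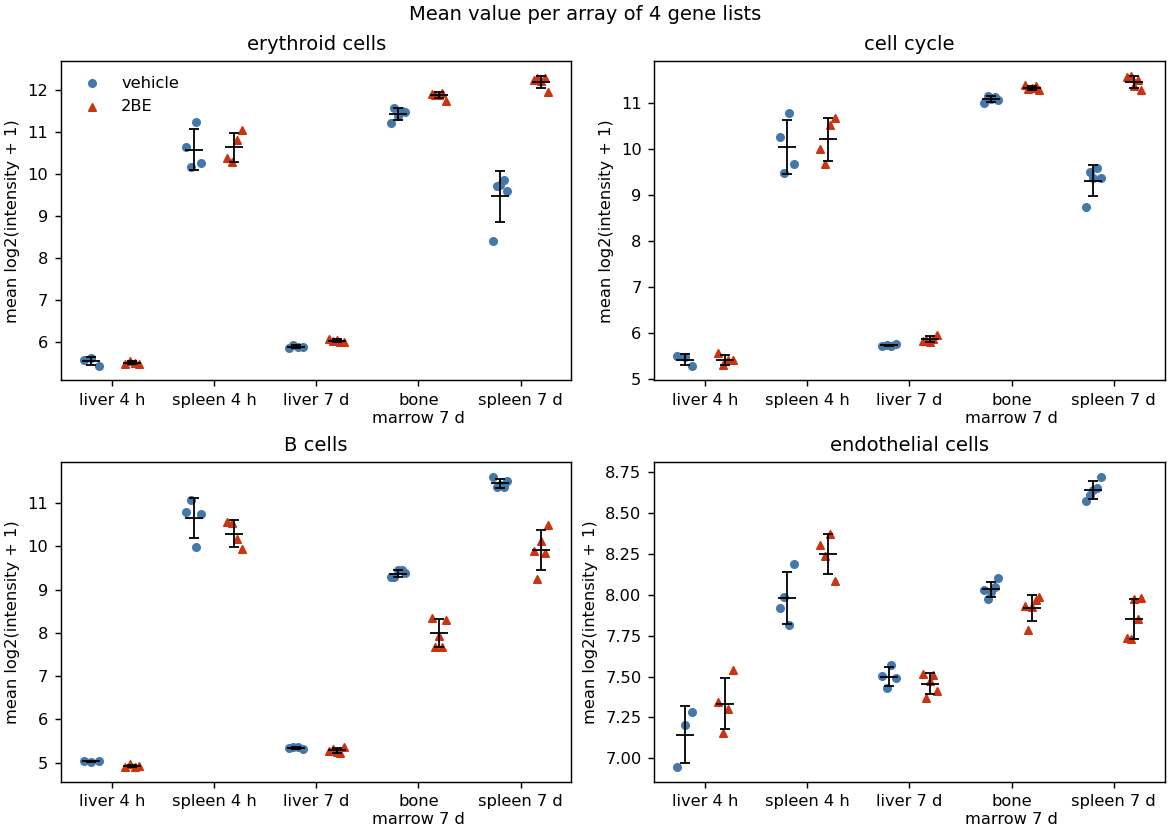
Mean log2(intensity + 1) over the genes of the erythroid, cell cycle, B cell and endothelial lists per array, by tissue and time (horizontal axis), with circles for vehicle, triangles for 2BE, and bars for mean and SD. In the spleen at 7 d the erythroid mean was 11.9 to 12.3 with 2BE against 8.40 to 9.87 with vehicle and the B cell mean 9.24 to 10.5 against 11.4 to 11.6, while in the marrow the B cell mean was 7.68 to 8.34 against 9.28 to 9.46.

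Of the 42 lists, 13 passed in none of the 5 comparisons with all arrays. Their lowest camera adjusted p-values were 0.229 for iron and haem handling (spleen at 4 h), 0.232 for coagulation and fibrinolysis (liver at 7 d), 0.291 for fatty acid oxidation and PPARa targets (spleen at 7 d) and 0.214 for hepatic cytochromes P450 and conjugation (liver at 4 h). For the next they were 0.242 for ER stress and integrated stress response (liver at 4 h), 0.212 for circadian clock (spleen at 4 h), 0.0649 for neutrophils (spleen at 4 h) and 0.0636 for haematopoietic stem and progenitor cells (spleen at 7 d). For the others they were 0.159 for hepatocytes (spleen at 7 d), 0.407 for cholangiocytes (liver at 7 d), 0.147 for adipocytes (spleen at 4 h), 0.0946 for bone cells (marrow) and 0.189 for skeletal muscle (spleen at 7 d). Leaving out 1 array brought some of these lists past the threshold: fatty acid oxidation and PPARa targets in the liver 4 h comparison without 2BE replicate 4 (adjusted p = 0.0377), hepatic cytochromes P450 and conjugation in the liver 4 h comparison without vehicle replicate 2 or 2BE replicate 4 (adjusted p = 0.00693 and 0.0377) and ER stress and integrated stress response in the liver 4 h comparison without vehicle replicate 3 (adjusted p = 0.00196). Others were circadian clock in the liver 7 d comparison without vehicle replicate 1 (adjusted p = 0.0490), neutrophils in the liver 4 h comparison without vehicle replicate 1 (adjusted p = 0.00353) and neutrophils in the spleen 4 h comparison without vehicle replicates 1 and 2 or 2BE replicates 3 and 4 (adjusted p = 0.0216, 0.000201, 0.0410 and 0.0314). Further ones were haematopoietic stem and progenitor cells in the spleen 7 d comparison without 2BE replicate 3 (adjusted p = 0.0495) and bone cells in the bone marrow 7 d comparison without 2BE replicates 4 and 5 (adjusted p = 0.0392 and 0.0372).

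**Figure D3:**
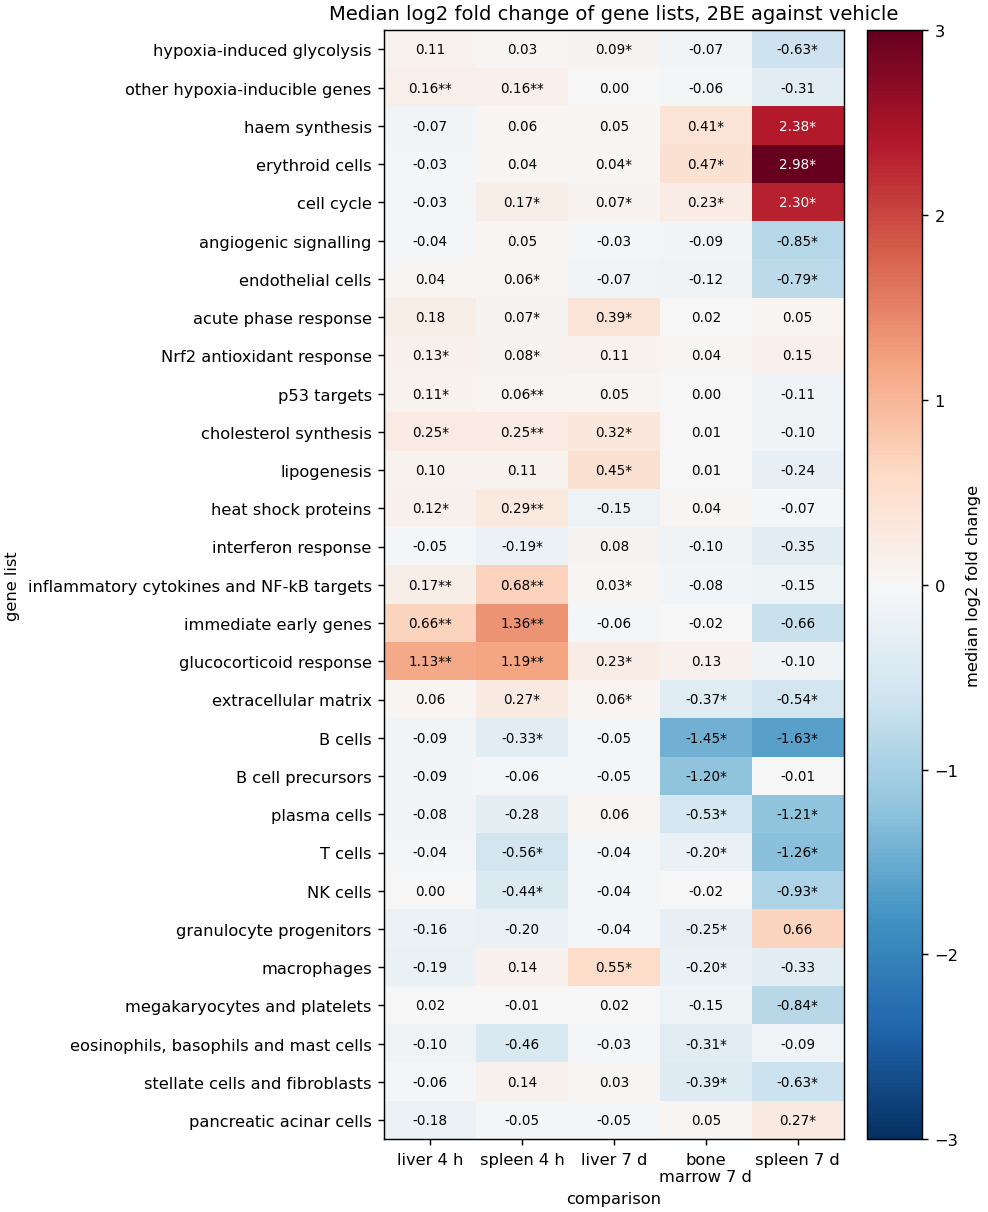
Median log2 fold change of 2BE over vehicle (colour scale, in log2 units) of the 29 gene and marker lists called in at least 1 comparison (vertical axis) in the 5 comparisons (horizontal axis), where 1 asterisk marks a camera adjusted p under 0.05 and a pair of asterisks the same also with an estimated correlation. The largest median was 2.98, for erythroid genes in the spleen at 7 d, and the lowest -1.63, for B cells in the same comparison.

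Differences between times were tested as the 7 d effect minus the 4 h effect in the same tissue. In the liver, the effect on Cdkn1a differed by -3.17 ± 0.60 (adjusted p = 0.0357) on the log2 scale and that on Arntl by -2.79 ± 0.47 (adjusted p = 0.0268). Hmox1 differed by -2.60 ± 0.28 (adjusted p = 0.000703) and Hspa1a by -2.41 ± 0.23 (adjusted p = 0.000207). Tgm1, a transglutaminase gene, differed by 1.83 ± 0.29 (adjusted p = 0.0228) in the other direction, and Hamp by -1.63 ± 0.47 (adjusted p = 0.208), which did not pass. Hmox1 and Hspa1a passed without each array in turn. Cdkn1a did not pass without liver 4 h vehicle replicates 1, 2 and 3, liver 4 h 2BE replicates 2, 3 and 4, liver 7 d vehicle replicates 2, 3 and 4 or liver 7 d 2BE replicates 3, 4 and 5 (adjusted p = 0.0528, 0.0883, 0.0658, 0.0890, 0.0710, 0.0907, 0.0866, 0.0801, 0.0861, 0.0780, 0.0812 and 0.0644, in this order). Arntl failed without liver 4 h vehicle replicates 1 and 2, liver 4 h 2BE replicate 4, liver 7 d vehicle replicates 2, 3 and 4 or liver 7 d 2BE replicates 3 and 4 (adjusted p = 0.0617, 0.0561, 0.0570, 0.0551, 0.0625, 0.0622, 0.0606 and 0.0587). The difference for Tgm1 was lost without liver 7 d vehicle replicate 3 or liver 7 d 2BE replicates 3 and 4 (adjusted p = 0.0558, 0.0557 and 0.0547). Of the genes given here, Cdkn1a (0.214), Tgm1 (0.0855) and Arntl (0.0674) did not pass with the replicate block, and with trend and robust Cdkn1a (0.0967) and Arntl (0.0533) did not. In all 49 genes differed, 18 with a higher and 31 with a lower effect at 7 d. The majority turned with the block (22 higher and 16 lower) and nearly vanished after a further quantile normalization (23 higher and 24 lower). Without liver 4 h vehicle replicate 1, liver 4 h 2BE replicates 1, 2 and 4, liver 7 d vehicle replicates 1, 2, 3 and 4 or liver 7 d 2BE replicates 3 and 4, the counts were 17, 111, 25, 18, 22, 21, 10, 6, 8 and 4, in this order.

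In the spleen, Hspa1b differed by -5.44 ± 0.49 (adjusted p = 5.4e-07) and Cxcl2 by -5.42 ± 0.29 (adjusted p = 1.6e-09), both risen at 4 h. Apol8 differed by 4.38 ± 0.63 (adjusted p = 3.1e-05), Apol11b by 4.102 ± 0.40 (adjusted p = 1.1e-06) and the erythroid gene Epb42 by 4.09 ± 0.41 (adjusted p = 1.4e-06). Apol8 and Epb42 had risen at 7 d. In all 9326 genes differed, 4663 with a higher and 4663 with a lower effect at 7 d, a balance that the low-value filter moved (2460 higher and 4401 lower).

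Tissue differences were tested likewise. At 4 h, the effect on Ccn1 was higher in the spleen than in the liver by 5.09 ± 0.37 (adjusted p = 4.2e-06) and that on Hspa1b by 4.29 ± 0.28 (adjusted p = 3.3e-06). Igfbp1 and Cyp2b10 responded more in the liver, with differences of -3.10 ± 0.47 (adjusted p = 0.00291) and -2.90 ± 0.42 (adjusted p = 0.00193). For Hmox1 the difference of -2.41 ± 0.64 (adjusted p = 0.0802) did not pass, but it did without spleen 4 h vehicle replicate 1 (adjusted p = 0.00940) and with all 44 arrays in 1 fit (adjusted p = 0.000268). In all 323 genes differed at 4 h, 170 higher and 153 lower in the spleen, and 214 without liver 4 h vehicle replicate 1. The majority turned with array medians subtracted (149 higher and 167 lower) and all 44 arrays in 1 fit (415 higher and 446 lower).

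At 7 d, 10370 genes differed between spleen and liver effects (4990 higher and 5380 lower in the spleen). The log2 difference was 4.095 ± 0.37 (adjusted p = 1.9e-10) for Apol8, -3.62 ± 0.55 (adjusted p = 2.2e-06) for Cyp4a14 and -3.53 ± 0.45 (adjusted p = 1.3e-07) for Marco. For Hamp it was 1.59 ± 0.34 (adjusted p = 0.000215). Between marrow and spleen 8167 differed (4541 higher and 3626 lower in the marrow), with Clec2d at 2.21 ± 0.23 (adjusted p = 3.8e-09) and Sowaha at -3.53 ± 0.28 (adjusted p = 2.2e-11). Between marrow and liver 1748 differed (730 higher and 1018 lower in the marrow), with Plek2 at 1.62 ± 0.17 (adjusted p = 1.0e-06), Cyp4a14 at -3.87 ± 0.55 (adjusted p = 3.4e-05) and Ppp1r3g at -3.43 ± 0.29 (adjusted p = 1.4e-08). Without liver 7 d vehicle replicate 4 the differences for Cyp4a14 were -2.74 and -2.98.

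Calls in pairs of comparisons, none of which share arrays, were set against the number that independent lists would share. Marrow and spleen at 7 d shared 1447 higher genes (554 for independent lists) and 1676 lower (621), with 91 opposite (1176). Their correlation across genes, which are not independent replicates, was 0.67. Liver and spleen at 4 h shared 108 higher (19.5) and 23 lower (4.27), with 7 opposite (18.5). Liver at 4 h and 7 d shared 42 higher (2.98) and 6 lower (0.559), with 3 opposite (2.60). Spleen at 4 h and 7 d shared 101 higher (195) and 211 lower (107), with 342 opposite (301). Liver and spleen at 7 d shared 24 higher (29.8) and 17 lower (14.1), with 53 opposite (43.7).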

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

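All tests of splits of the arrays and of the patterns below were chosen after the results had been seen, except the test of collagen genes in the marrow. The clock test was in addition redefined after its first form had been seen.

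Single arrays far from the rest of their group were sought among the named genes. In 37 of 399 groups of 4 or 5 arrays (9.27%) the extreme value lay apart by Dixon's criterion at the 5% level, which chance alone reaches in about 1 in 20 groups. In the spleen at 7 d, vehicle replicate 1 lay below the other vehicle arrays on the log2 scale for Apol8 (5.57), Sowaha (4.09), Mageb16 (5.01), Samd11 (5.52), Epb42 (6.33), Tspan8 (5.54), Sox6 (6.25), Kel (7.64), Icam4 (6.18), Abcb10 (9.16), Urod (10.13), Alas2 (12.28), Ccne2 (6.45), Kif11 (7.05), Ccnb2 (8.48), Mki67 (10.51), Mxi1 (8.82) and Gclm (9.59). Most are erythroid and proliferation genes, and genes of 1 cell type vary together, so these are not separate events. 2BE replicate 5 lay below the other 2BE arrays of the spleen at 7 d for Apol8 (10.78), Samd11 (9.93), Tspan8 (10.53), Sox6 (11.33), Kel (12.27), Mxi1 (10.52) and Nqo1 (8.27). The others were Cxcl2 in liver 4 h 2BE replicate 4 (6.95, above), Tbx21 in spleen 4 h 2BE replicate 1 (7.12, above), Cyp4a14 in liver 7 d vehicle replicate 4 (5.87, below) and Id1 in liver 7 d vehicle replicate 3 (7.98, below). They were followed by Osgin1 in liver 7 d 2BE replicate 2 (8.78, below), Smad7 in liver 7 d vehicle replicate 3 (7.62, below), Pck1 in liver 7 d 2BE replicate 1 (12.72, below) and Tat in liver 7 d vehicle replicate 2 (12.58, below). The last were Tfrc in liver 7 d 2BE replicate 2 (8.77, above), Tfrc in bone marrow 7 d 2BE replicate 2 (13.55, below), Cd28 in spleen 7 d vehicle replicate 2 (9.35, above) and Cd3g in spleen 7 d 2BE replicate 2 (7.10, below). Without 2BE replicate 5 of the spleen at 7 d, 12435 genes changed there.

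Differences between times or tissues passed their own test for 49 genes between liver times, 9326 between spleen times, 10370 between spleen and liver at 7 d, 8167 between marrow and spleen, 1748 between marrow and liver and 323 between spleen and liver at 4 h. Between liver times the log2 differences were 1.83 ± 0.29 for Tgm1, 1.74 ± 0.28 for Cd24a, 1.66 ± 0.23 for Nmrk1, -3.17 ± 0.60 for Cdkn1a, -2.79 ± 0.47 for Arntl and -2.60 ± 0.28 for Hmox1, where ± gives the SE. Cd24a was lost without liver 7 d vehicle replicates 3 and 4 or liver 7 d 2BE replicate 4 (adjusted p = 0.0501, 0.0528 and 0.0547), and losses of Tgm1, Cdkn1a and Arntl are listed with the time differences. Between spleen times they were 4.38 ± 0.63 for Apol8, 4.102 ± 0.40 for Apol11b, 4.09 ± 0.41 for Epb42, -5.44 ± 0.49 for Hspa1b, -5.42 ± 0.29 for Cxcl2 and -5.14 ± 0.98 for Fabp4, while the adipocyte gene Adipoq was at 2.18 at 4 h and -3.14 at 7 d (Fabp4 -4.52 without spleen 7 d vehicle replicate 2). For spleen minus liver at 7 d they were 4.095 ± 0.37 for Apol8, 4.08 ± 0.21 for Tlcd4, -3.62 ± 0.55 for Cyp4a14 and -3.53 ± 0.45 for Marco. For marrow minus spleen they were 2.21 ± 0.23 for Clec2d, 2.20 ± 0.30 for Klra8, -3.53 ± 0.28 for Sowaha and -3.49 ± 0.34 for Mageb16. For marrow minus liver they were 1.62 ± 0.17 for Plek2, 1.45 ± 0.27 for Osgin1, -3.87 ± 0.55 for Cyp4a14 and -3.43 ± 0.29 for Ppp1r3g. For spleen minus liver at 4 h they were 5.09 ± 0.37 for Ccn1, 4.29 ± 0.28 for Hspa1b, -3.10 ± 0.47 for Igfbp1 and -2.90 ± 0.42 for Cyp2b10.

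Among the 9160 probe sets with no gene in the annotation, the same tests called 156 in the liver at 4 h (131 higher and 25 lower), 220 in the spleen at 4 h (167 and 53), 28 in the liver at 7 d (24 and 4), 711 in the marrow (169 and 542) and 4469 in the spleen at 7 d (2446 and 2023).

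Other splits of the arrays of each comparison into groups of the same sizes were tested, all 35 at 4 h and 100 drawn at 7 d, the real split included. The real split alone gave as many changed genes in the liver at 7 d (136, highest other 1), the marrow (3651, highest other 0) and the spleen at 7 d (11712, highest other 8920). Chance can be excluded there. In the spleen at 4 h, 3 of 35 splits gave as many as 938 (highest other 1154), so chance cannot be excluded for that count. Genes changed at least 2-fold were as many in the real split alone in the spleen at 4 h, liver at 7 d, marrow and spleen at 7 d (137, 35, 94 and 1896, with 74, 0, 0 and 785 in the highest other), so chance can be excluded for these counts. Many splits gave as many lists (number called and highest other in brackets), so chance cannot be excluded. At 4 h they were 21 of 35 in the liver (8, 19) and 14 of 35 in the spleen (16, 20). At 7 d they were 25 of 100 in the marrow (12, 18) and 22 of 100 in the spleen (14, 19). In the liver at 7 d, 2 of 100 gave as many as 10 (highest other 10). As 0 lists passed with an estimated correlation or fry, chance stays open there. In the liver at 4 h only 8 splits part all 3 same-numbered pairs, too few for a share under 0.05, and they gave 821 in the real split and 0 in the others. Its 35 splits ignore the pairs, with 821 changed genes (highest other 625) and 133 at least 2-fold (100).

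For differences, arrays were reassigned to arms within each set in 2 draws of 100, and the larger share is given. Chance can be excluded for the spleen times (9326, 1 of 100, highest other 5054), for spleen and liver at 7 d (10370, 1 of 100, highest other 8909) and for marrow and liver (1748, 1 of 100, highest other 1305). For spleen and liver at 4 h (323, 2 of 100, highest other 538) and the liver times (49, 3 of 100, highest other 116) the draws ignored the possible pairs of the liver at 4 h, so they leave chance open. A structure of the samples beside the arms, the instability of a small count or splits that largely reversed the arms at 1 time could give the 116. None of these was tested. For marrow and spleen, 6 of 100 splits gave as many as 8167 (highest other 9952; 3 of 100 in the other draw), so chance cannot be excluded.

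In the spleen at 7 d, lymphocyte, endothelial, angiogenic and glycolysis lists were lower while erythroid genes were higher. Had erythroid cells diluted all other cells alike, B cell and macrophage scores would fall equally. B cells fell by 1.54 and macrophages by 0.38, a difference of -1.16 (log2, exact two-sided permutation p = 0.00794, the smallest 5 against 5 arrays can give). Both lists were picked knowing this, so a smaller dilution or a change in macrophages themselves stays open. If the authors' normalization had pressed genes of this intensity down, other genes of the same mean intensity would be down alike, but 10000 matched random lists had medians of -0.23 to 0.05 (middle 95%), against -0.92 for the union of the 6 lists (92 genes), which argues against it. These lists were picked because they fell, so their own low median is no evidence; in the same test over all 42 lists, each of the 6 lay below its matched lists (adjusted p from 0.00120 to 0.0216). A loss of lymphocytes, or a shift between cell types in the part of the spleen that was taken, may remain as hypotheses and were not tested.

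In the marrow at 7 d, B-lineage lists were lower. Dilution by erythroid cells would lower neutrophil markers too. The B-lineage score (17 genes) minus the neutrophil score was -1.33 (exact two-sided permutation p = 0.00794, the smallest possible), with neutrophils at -0.01 (p = 0.881). Neutrophils were picked knowing this, and macrophages and T cells fell, so a smaller dilution stays open. Less bone and stroma in the treated samples could also lower both B-lineage and collagen genes (4 collagen genes, -1.04, exact two-sided permutation p = 0.0159). Within the arms their deviations correlated at r = 0.67 (two-sided permutation p = 0.185) and rho = 0.60 (p = 0.197; adjusted p = 0.197 over both) over 10 arrays, and r was 0.23 without the 2 arrays farthest from the median, so this explanation cannot be told apart from an effect on B cells: the correlation missed the threshold and rested on those 2 arrays.

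At 7 d the clock list was not called (camera adjusted p = 0.297, 0.485 and 0.440 in liver, marrow and spleen), but 4 morning genes (Arntl, Npas2, Clock and Cry1) were lower on average, and a different time of day of collection, which would also raise 10 evening genes, may be the cause. In the liver, evening genes were at 0.46 (exact two-sided permutation p = 0.0397, adjusted p = 0.0595) and morning genes at -0.66 (p = 0.0159, adjusted p = 0.0317), in line with such a shift in their directions. In the marrow evening genes were at 0.075 (exact two-sided permutation p = 0.413) and morning genes at -0.40 (p = 0.00794, adjusted p = 0.0238), and in the spleen at -0.091 (p = 0.452) and -0.69 (p = 0.00794, adjusted p = 0.0238). There the collection time and an effect of 2BE on Arntl and its partners cannot be told apart, because the labels give no clock time. In its first form, evening minus morning genes, the score differed by 1.12 in the liver, 0.47 in the marrow and 0.60 in the spleen at 7 d (exact two-sided permutation, adjusted p = 0.0397, 0.0198 and 0.0198), and by -0.69 and 0.04 in liver and spleen at 4 h (adjusted p = 0.143 and 0.629).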

How the results depend on the processing

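The alternatives were chosen before the data were examined, except logs with no pseudocount, tested after they had been seen, under which no count moved by over 1.5 times. Of 4149 repeats of named gene calls under an alternative, 3936 stayed on their side of the threshold, 204 lost and 9 gained it, and 0 changed direction. Of 2538 repeats for named differences 2448 stayed, 74 lost and 16 gained it. Of 1167 for lists 1006 stayed, 68 lost and 92 gained it and 1 turned: granulocyte progenitors in the spleen at 4 h, at 0.64 without spleen 4 h vehicle replicate 3 against -0.20. All 41 named calls of the marrow, 57 of 58 of the spleen at 7 d, 32 of 33 of the spleen at 4 h, 22 of 36 of the liver at 4 h and 6 of 28 of the liver at 7 d held under every alternative run. No scaling moved the median of all genes by over 0.1. With only the arrays of the 2 groups compared, which leaves fewer arrays for the spread, 176 genes changed in the liver at 4 h (821 before; 75 against 133 at least 2-fold), 508 in the spleen at 4 h (938) and 244 in the liver at 7 d (136). Array weights gave 406 in the liver at 7 d, 13 lists in the liver at 4 h (8) and 86 differences between liver times (49). Trend and robust gave 17 genes changed at least 2-fold in the liver at 7 d (35). The low-value filter, which tests fewer genes, left 5 lists in the liver at 4 h, 6 in the liver at 7 d (10) and 8 in the spleen at 7 d (14). With an estimated correlation 4 lists passed in the liver at 4 h, 7 in the spleen at 4 h (16) and 0 in each comparison at 7 d (10, 12 and 14 with camera). Fry called 10 in the spleen at 4 h, 0 in the liver at 7 d and 29 in the spleen at 7 d. At an unadjusted p under 0.05, camera with an estimated correlation called 3, 6 and 2 in liver, marrow and spleen at 7 d and fry 7 in the liver at 7 d. With all 44 arrays in 1 fit, 1138 genes differed between marrow and liver (1748) and 861 between spleen and liver at 4 h (323). Limited to genes changed 2-fold in both, shared genes were 25 higher and 0 lower for liver and spleen at 4 h, 12 and 3 for the liver times, 5 and 3 for the spleen times, 4 and 59 for marrow and spleen and 3 and 1 for liver and spleen at 7 d. A further quantile normalization gave 39 shared lower genes for liver and spleen at 4 h (23), 16 for the liver times (6) and 345 for the spleen times (211), and the filter 10 for the liver times. Why these counts moved was not tested. With the replicate block, 471 genes and 13 lists passed in the liver at 4 h, where numbers may pair arrays, and 23 genes at least 2-fold in the liver at 7 d (35). Elsewhere the numbers were not taken to pair arrays: correlations of same-numbered arrays were -0.38 to 0.54 in the spleen at 4 h, -0.16 to 0.08 in the liver at 7 d, -0.09 to 0.16 in the marrow and -0.16 to 0.24 in the spleen at 7 d. With treatment and number as 1 mouse (random block; correlation 0.0556 at 7 d and 0.0473 at 4 h), no count moved by over 1.5 times. Leaving out 1 array gave 466 to 1090 changed genes and 7 to 13 lists in the liver at 4 h, 36 to 250 genes, 8 to 63 at least 2-fold and 6 to 13 lists in the liver at 7 d, 4 to 111 differences between liver times and 214 to 366 between spleen and liver at 4 h. Elsewhere no count moved by over 1.5 times. Each such array is named with its comparison. Without detection values, signal over background could not be assessed.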

Other observations

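No test in this part was chosen after a result was seen. In the spleen at 7 d, where 64.4% of all genes changed, antioxidant response genes moved in both directions. Of 23 measured Nrf2 list genes 8 rose and 6 fell, also adjusted over the list alone (median log2 fold change 0.15, camera adjusted p = 0.677). Gclm, the regulatory subunit of the rate-limiting enzyme of glutathione synthesis, rose 4.81-fold (2.27 ± 0.16, adjusted p = 2.5e-08). The quinone reductase gene Nqo1 rose 3.67-fold (1.88 ± 0.18) and Gclc, the catalytic subunit that pairs with Gclm, rose 2.97-fold (1.57 ± 0.12). Iron and haem handling had 11 of 28 genes higher and 9 lower, also adjusted over the list alone (camera adjusted p = 0.594). Blvrb, which encodes a biliverdin reductase, rose 4.13-fold (2.05 ± 0.19), and the transferrin receptor gene Tfr2 rose 3.64-fold (1.86 ± 0.21), with its other probe set at 2.89. In each of these genes all 5 2BE arrays lay above all 5 vehicle arrays. Of 24 other hypoxia-inducible genes 3 rose and 11 fell, also adjusted over the list alone (median log2 fold change -0.31, camera adjusted p = 0.0853; fry adjusted p = 1.7e-06). Mxi1, an antagonist of Myc, rose 3.19-fold (1.67 ± 0.17).

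In the bone marrow at 7 d, Gpam, Elovl6 and Arntl fell (5 arrays per arm). Gpam, the first enzyme of glycerolipid synthesis, fell 1.92-fold (-0.94 ± 0.087, adjusted p = 1.4e-05), and the fatty acid elongase gene Elovl6 fell 1.58-fold (-0.66 ± 0.079). Lipogenesis as a list did not shift, with 6 of 18 genes higher and 4 lower, and 6 and 5 adjusted over the list alone (camera adjusted p = 0.756). Arntl, a core clock transcription factor gene, fell 2.05-fold (-1.03 ± 0.15, adjusted p = 0.000339). The clock list had 0 of 15 genes higher and 2 lower, as it did adjusted over the list alone (camera adjusted p = 0.485).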
